A study of Mus musculus with 24 samples.

How the data were processed

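Gene expression was measured in the gastrocnemius-soleus muscle complex of female mice aged 5 weeks, on 24 Illumina mouse bead arrays, 6 in each of 4 groups: wild type or transgenic, unexercised or exercised. Total RNA was made into biotinylated cRNA, per the labels' protocols. Each array was assigned to its group from its title in the labels, and the replicate numbers are those of the labels.

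The deposited table gives 1 signal intensity per probe and array on a linear scale, not normalised between arrays, per the file headers. Beside each intensity stands the deposited detection p-value, the share of negative control beads at least as bright. The software that summarised the beads and any background subtraction are not given in the sources used here. A second deposited table holds log2 values normalised between arrays by the submitters, whose processing notes name R 3.1.1 and limma 3.20.8 without the steps. Set against the values computed here from the intensities, those log2 values differed by at most 0.0269, so their scale and direction were taken as known. They were used as an alternative. Array slides and scan dates are not given in the sources used here, so slide could not be entered as a block.

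The intensities were background-corrected and quantile-normalised with neqc of limma 3.58.1 in R 4.3.3, with an offset of 16, using the detection p-values because the table holds no control probes. A probe was kept if its detection p was under 0.05 on at least 6 arrays, which left 21788 of 45281 probes. Of the probes in the file, 34885 had 1 gene symbol in the platform annotation, 18 had several and 10378 had none. No symbol needed updating (0 updated). For each symbol the probe with the highest mean over all arrays was kept, and probes without a single symbol stayed as themselves. This gave 14984 features, called genes below, 11574 of them with a symbol. Chromosomes and gene order came from a RefSeq gene table of GRCm38.p6, matched by the Entrez ID in the platform annotation. The files name no genome build, so no coordinates are given.

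Whether shared replicate numbers pair the arrays was checked by the correlation of their deviations from the group means. At rest all 3 shared numbers gave over 0.1 (0.347, 0.412 and 0.687), so the blocked values stand beside those results. In the other comparisons at least 1 shared number did not. The block gives each number its own term, so fewer residual degrees of freedom are left. An array whose number no other array shares then adds nothing to a contrast. A call can therefore end with the block through lost precision alone.

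A linear model with 4 group means was fitted to all 24 arrays with lmFit and eBayes, so that the groups shared 1 estimate of the spread. The contrasts were exercise in wild type, exercise in transgenic mice, their difference (the interaction), genotype at rest, genotype after exercise, and the mean exercise and mean genotype effects. Tests were two-sided, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the 14984 genes of a contrast. The limma adjusted p-values are given throughout. A probe not detected on any array of a group has only a bound there. The bound sets the bright group's mean against the dim group's mean of, per array, the higher of the lowest detected signal and the probe's own signal.

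Of the gene lists written, 28 were tested with camera, which compares a list with all other genes, at a preset correlation of 0.01 and again with an estimated correlation. The lists were also tested with fry, which asks whether a list's genes move on balance 1 way, or, as its mixed test, in either direction. Adjustment was over the 28 lists within a contrast. Counts of called members are given over all genes and adjusted over the list alone.

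The genes named were set by a rule. It took the 10 largest rises and 10 largest falls among called genes with a symbol that is not a clone or predicted-gene name. For the contrasts averaged over genotypes or exercise states it took 5 and 5. Where nothing was called it took the 3 genes with the smallest p. It added up to 4 members with the smallest p from each list described, and Itga7 and Itgb1 always. The grouping, tests, lists, naming rule and 16 alternatives were chosen before the data were examined, along with leaving out each of the 24 arrays singly. A further 7 alternatives were chosen after seeing the data. They used the array means of the lymphocyte marker and slow fibre lists as covariates, 2 hidden factors, or subsets of arrays split at the widest gap in either mean.

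The fit was tested on simulated data for exercise in wild type, with the 14984 real genes, 6 arrays per group and 100 changed genes of each size. With independent noise it recovered 71% of changes of log2 1.0 and 22% of changes of log2 0.5, with 0 wrong signs and 1 false call. With noise shaped like the lymphocyte and slow fibre differences between arrays it recovered 75% and 22%. Adding both list means as covariates raised these to 93% and 40%, and the false calls from 2 to 6. That noise was made from the same 2 list means, so the gain was fixed in advance. It does not show that the covariates improve the fit of the real data. These shares hold for that many changed genes, since the adjustment is stricter where fewer genes change. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9. The precision of array values is limited by the number of arrays, and the p-values measure the spread between these samples.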

Results

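The study asked how extra α7 integrin, a laminin receptor of the muscle fibre membrane, alters gene transcription in mouse muscle after damaging exercise. Wild-type mice (WT) were compared with mice carrying an α7BX2 integrin transgene (transgenic, TG). In each genotype 6 mice stayed unexercised (at rest) and 6 ran downhill at a slope of 20 degrees for 40 min at 17 m/min. A warm-up of 2 min took the speed up from 10 m/min. Muscle was taken 3 h after the run, so the 24 arrays show an early response. Median signal per array ranged from 105.2 to 137.9, and 40.2% to 46.3% of probes were detected. Over the 14984 genes tested, the correlation between pairs of arrays ranged from 0.909 to 0.991.

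The arrays differed widely in marker genes of lymphocytes and of slow fibres. The mean of the lymphocyte marker list stood high in 11 of the 24 arrays, 5 of 12 unexercised and 6 of 12 exercised. By group it was 7.21 ± 1.76 (log2 signal, mean ± SD, n = 6) in wild type at rest, 6.88 ± 1.95 in wild type after the run, 6.66 ± 1.55 in transgenic at rest and 7.66 ± 1.77 in transgenic after the run. The slow fibre list, genes of oxidative type I fibres, stood high in 10 arrays. Its group means were 11.1 ± 0.76, 11.5 ± 0.74, 11.3 ± 0.70 and 11.2 ± 0.63 in the same order. Residual variation within groups was concentrated, with 53.1% on its first component and 18.7% on its second.

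**Figure D1:**
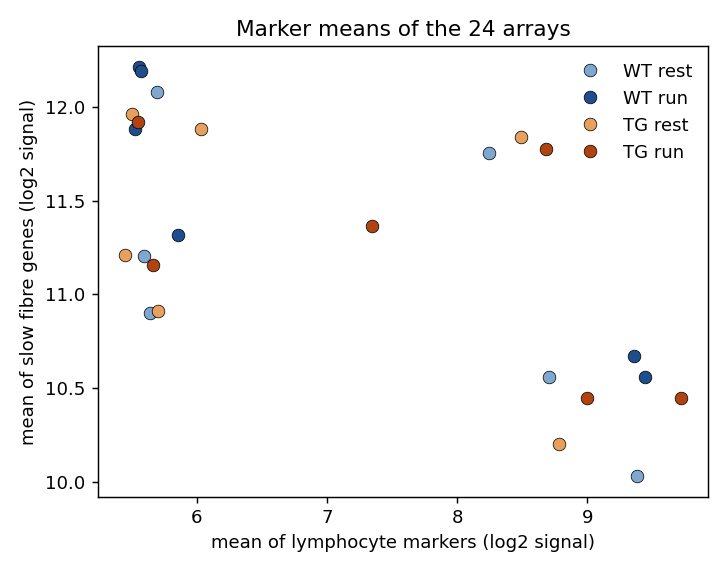
Mean log2 signal of the lymphocyte markers (horizontal axis) and of the slow fibre genes (vertical axis) in each of the 24 arrays, coloured by group. The 11 arrays high in lymphocyte markers come from all 4 groups.

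Itga7, which encodes the α7 integrin chain, gave similar signals in all groups. Its brighter probe read 8.87 ± 0.42 (log2, mean ± SD, n = 6) in wild type at rest, 8.86 ± 0.65 in wild type after the run, 9.09 ± 0.55 in transgenic at rest and 8.86 ± 0.61 in transgenic after the run. The mean genotype difference was 0.11 (SE 0.22, limma adjusted p = 1.0), and a second Itga7 probe gave 0.057 (SE 0.235). Itgb1, the β1 chain that pairs with α7, differed by 0.0085 (SE 0.14). All 4 probes of these genes were detected on all 24 arrays. Whether the Itga7 probes match the transgene's transcript is not given in the sources used here, so these values do not check the genotype labels. Across both exercise states, the integrin-laminin and dystrophin-glycoprotein adhesion genes had a median genotype difference of 0.0069 over 34 members, with 0 called by limma over all genes and 0 adjusted over the list alone (camera adjusted p = 1.0).

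The first comparison asked what the run changed on average over both genotypes. The metallothioneins Mt1 and Mt2, small metal-binding proteins induced by glucocorticoids, metals and oxidative stress, rose in muscle 3 h after the run. Mt1 rose by 1.34 on the log2 scale (SE 0.16, 2.53-fold, adjusted p = 0.00016) and Mt2 by 1.58 (SE 0.23, 2.99-fold, adjusted p = 0.00515). Mt1 read 12.95 ± 0.37 and 12.78 ± 0.48 in wild-type and transgenic mice at rest against 14.18 ± 0.42 and 14.23 ± 0.27 after the run (n = 6 each). Mt2 read 6.30 ± 0.70 and 6.47 ± 0.59 at rest against 7.99 ± 0.65 and 7.93 ± 0.46. These were the only 2 of 14984 genes called, both higher, while 597 genes had an unadjusted p under 0.05. In this and every other contrast, that number was below the share of 0.05 of all genes expected if none changed.

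**Figure D2:**
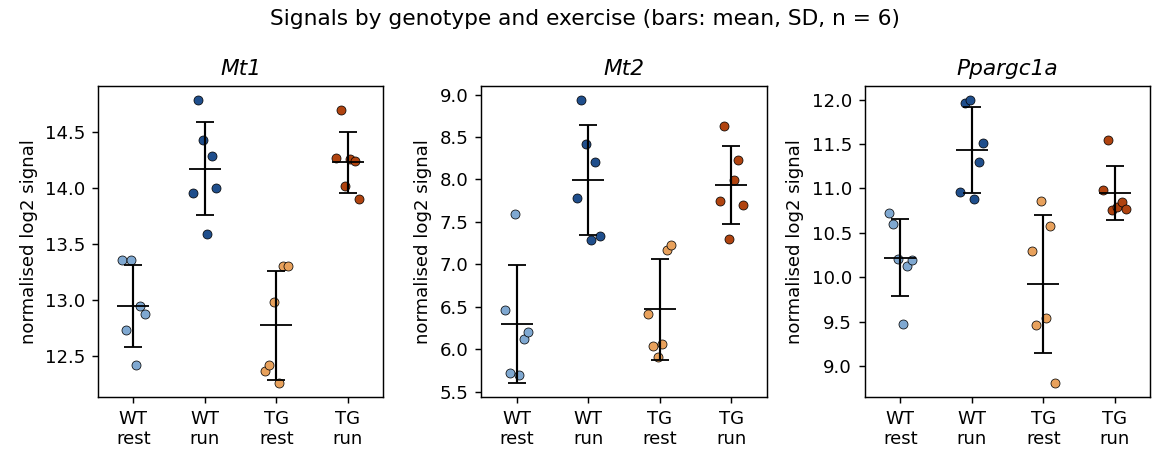
Normalised log2 signal of Mt1, Mt2 and Ppargc1a in each array by genotype and exercise; points are arrays, bars give the mean and SD of 6 arrays. Mt1 means rise from 12.95 to 14.18 in wild type and from 12.78 to 14.23 in transgenic mice; Ppargc1a did not pass the test.

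The metallothionein and glucocorticoid-responsive list stood higher after the run in 13 of its 16 measured members, with a median of 0.20 (camera adjusted p = 6.26e-08; adjusted p = 0.127 with an estimated correlation). In it 2 members were called over all genes and 4 rose adjusted over the list alone. Fkbp5, a glucocorticoid-induced chaperone of the steroid receptor, differed by 0.92 (SE 0.20, adjusted p = 0.228) and Tsc22d3 by 0.39 (SE 0.13, adjusted p = 0.777). Heat shock proteins and chaperones were higher in 23 of 24 members, with a median of 0.19 (camera adjusted p = 1.56e-09; adjusted p = 0.127 with an estimated correlation). None was called over all genes (0 of 24) and 5 rose adjusted over the list alone. Hspa1a, the inducible 70 kDa chaperone, differed by 1.64 (SE 0.44, adjusted p = 0.469), Hspa1b by 1.13 (SE 0.36), Hspb1 by 0.51 (SE 0.15) and Hsp90aa1 by 0.52 (SE 0.17).

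Immediate early genes, the first transcription factors made after a stimulus, were higher in 17 of 22 members (median 0.18, camera adjusted p = 0.000159; adjusted p = 0.232 with an estimated correlation). Atf3 differed by 1.87 (SE 0.42, adjusted p = 0.252) and was the 1 member called adjusted over the list alone, against 0 over all genes. The immediate early median was 0.026 in the 11 lymphocyte-high arrays (camera adjusted p = 0.802) and 0.018 in the 14 slow-low arrays (0.347). Cytokines and chemokines had a median of 0.23 over 23 members (camera adjusted p = 3.67e-05; adjusted p = 0.232 with an estimated correlation), with 0 called over all genes and 1 adjusted over the list alone. Among them Socs3, a feedback inhibitor of cytokine signalling, differed by 0.65 (SE 0.19, adjusted p = 0.554) and the chemokine Ccl9 by 0.60 (SE 0.21, adjusted p = 0.886). The integrated stress and unfolded protein response list was higher in 12 of 15 members (median 0.12, camera adjusted p = 0.00077; adjusted p = 0.127 with an estimated correlation), with 0 called over all genes and 1 adjusted over the list alone. Hsp90b1 differed by 0.32 (SE 0.086) and Hspa5 by 0.48 (SE 0.18).

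Neutrophil markers had a median of 0.64 over 12 members (camera adjusted p = 1.81e-05; adjusted p = 0.463 with an estimated correlation), with 0 called by either count. The same list differed by 1.22 between the 11 arrays high and the 13 low in lymphocyte markers, and by -1.20 between the 10 arrays high and the 14 low in slow fibre genes. Its median was 0.054 in the 13 lymphocyte-low arrays (camera adjusted p = 0.54) and 0.0147 in the 10 slow-high arrays (0.8). Circadian clock genes were lower in 10 of 12 members (median -0.14, camera adjusted p = 0.00752; adjusted p = 0.718 with an estimated correlation), with 0 called over all genes and 2 lower adjusted over the list alone. Dbp differed by -0.46 (SE 0.13) and Ciart by -0.61 (SE 0.20); the clock list differed by 0.45 between arrays high and low in slow fibre genes. The integrin-laminin and dystrophin-glycoprotein adhesion genes had a median of -0.018 over 34 members (camera adjusted p = 0.677). Their 1 member called adjusted over the list alone was Itga9, at 0.35 (SE 0.077, adjusted p = 0.252 over all genes). Fry called 0 of 28 lists on balance in this and every other contrast. Its mixed test called 2 lists here, the metallothionein list (adjusted p = 9.76e-06) and the fuel metabolism list (adjusted p = 0.00427). Camera called 13 lists at the preset correlation and 0 with an estimated one, and the latter count was 0 in every contrast. With the lymphocyte and slow fibre means as covariates, chosen after seeing the data, 31 genes were called, 22 higher and 9 lower, and Mt1 and Mt2 were both kept. Without wild-type array 6 of the exercised group, 4 genes were called. In subsets of arrays, the integrated stress call ended in lymphocyte-low (0.0633) and slow-low arrays (0.1), the clock call in lymphocyte-low (0.5) and slow-high arrays (0.184), and the cytokine call in lymphocyte-high arrays (0.0513).

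In wild-type mice alone, stress and fuel metabolism genes stood higher by camera at the preset correlation after the run, and no single gene passed the test. With an estimated correlation these lists were not called (adjusted p = 0.0778 for chaperones and for metallothioneins, 0.0811 for fuel metabolism and 0.317 for immediate early genes). The 3 genes with the smallest p were Mt1, Mt2 and Pdk4, a kinase that turns off pyruvate oxidation during exercise and fasting. Mt1 differed by 1.22 (SE 0.22, adjusted p = 0.161), Mt2 by 1.70 (SE 0.33, adjusted p = 0.257) and Pdk4 by 0.95 (SE 0.23, adjusted p = 1.0). All 24 heat shock and chaperone genes were higher, with a median of 0.26 (camera adjusted p = 2.48e-10; adjusted p = 0.0778 with an estimated correlation), and 0 were called by either count. Hspa1a differed by 2.04 (SE 0.62), Hspa1b by 1.44 (SE 0.51), Hspb1 by 0.48 (SE 0.22) and Bag3 by 0.27 (SE 0.13). The chaperone list itself differed by 0.27 between arrays high and low in slow fibre genes.

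The metallothionein and glucocorticoid-responsive list had a median of 0.23 in wild type, with 14 of 16 members higher (camera adjusted p = 4.98e-09; adjusted p = 0.0778 with an estimated correlation). Over all genes 0 members were called, and 3 rose adjusted over the list alone. Exercise-responsive fuel metabolism genes were higher in 16 of 22 members (median 0.054, camera adjusted p = 0.00221; adjusted p = 0.0811 with an estimated correlation), with 0 called over all genes and 2 adjusted over the list alone. Ppargc1a, a coactivator of mitochondrial biogenesis, differed by 1.21 (SE 0.29, adjusted p = 1.0), Ucp3 by 0.50 (SE 0.23) and Irs2 by 0.40 (SE 0.16). The camera call of this list ended without wild-type rest array 6 (adjusted p = 0.0537). Immediate early genes had a median of 0.16 over 22 members (camera adjusted p = 0.000897; adjusted p = 0.317 with an estimated correlation), with 0 called over all genes and 1 adjusted over the list alone, and Atf3 differed by 2.19 (SE 0.59).

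Growth arrest and p53 target genes had a median of 0.14 over 15 members (camera adjusted p = 0.0164; adjusted p = 0.0778 with an estimated correlation), with 0 called by either count. Rrad differed by 0.89 (SE 0.37) and Cdkn1a by 0.34 (SE 0.19), and the camera call ended without wild-type rest array 6 (adjusted p = 0.0753) or wild-type exercised array 6 (adjusted p = 0.0888). All 13 slow fibre genes were higher (median 0.40, camera adjusted p = 0.002; adjusted p = 0.686 with an estimated correlation) and all 12 adipocyte markers lower (median -0.46, camera adjusted p = 0.000477; adjusted p = 0.546 with an estimated correlation), with 0 called by either count in both. Myl6b differed by 0.74 (SE 0.58), Tnni1 by 0.58 (SE 0.56) and Adipoq by -0.58 (SE 0.45). Beside these, 3 of 6 exercised and 2 of 6 unexercised wild-type arrays were high in slow fibre genes, and 2 against 3 were high in lymphocyte markers. The adipocyte list differed by 0.88 between arrays high and low in lymphocyte markers and by -0.84 between those high and low in slow fibre genes. The slow fibre call ended without wild-type rest array 10 (adjusted p = 0.186), and the adipocyte call without wild-type exercised array 3 (0.109) and with both list means as covariates (0.15). The slow fibre median turned to -0.156 in lymphocyte-high arrays (camera adjusted p = 0.637) and to -0.106 with the replicate block (0.443). The adipocyte median turned to 0.216 in lymphocyte-high arrays (0.108) and to 0.0297 in slow-low arrays (0.747). With array weights the immediate early (0.0609), fuel metabolism (0.095) and p53 target (0.156) calls ended. Limma called 0 of 14984 genes, and 322 had an unadjusted p under 0.05. Without wild-type rest array 3, 1 gene was called, Mt2 (adjusted p = 0.028), and with array weights Mt1 (0.013) and Mt2 (0.0228) were called. In subsets of arrays, the fuel metabolism call ended in lymphocyte-low (0.42) and slow-high arrays (0.086), the immediate early call in lymphocyte-high (0.399) and slow-low arrays (0.266), the chaperone call in lymphocyte-high arrays (0.109), the slow fibre call in slow-low arrays (0.0542) and the p53 target call in all 4 subsets (0.0542 to 0.146).

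In transgenic mice the run raised Mt1 by 1.46 on the log2 scale (SE 0.22, 2.74-fold, adjusted p = 0.013). Groups of myeloid, matrix and stress genes stood higher on average and clock genes lower by camera at the preset correlation. Each of these lists had an adjusted p = 0.46 with an estimated correlation. Mt1 was the 1 gene called, with 0 lower, and 713 genes had an unadjusted p under 0.05. The call ended without transgenic rest array 3 (adjusted p = 0.0671), rest array 8 (0.0668), rest array 11 (0.0633) or exercised array 3 (0.0645), with Mt1 differing by 1.35 to 1.39. The call also ended with median scaling (adjusted p = 0.118) and with only these 2 groups in the fit (adjusted p = 0.167). Mt2 differed by 1.47 (SE 0.33, adjusted p = 0.605) and Fkbp5 by 0.98 (SE 0.28), while Per1, a clock gene induced by glucocorticoids, differed by -0.84 (SE 0.24). The metallothionein and glucocorticoid-responsive list had a median of 0.21 over 16 members (camera adjusted p = 0.00342; adjusted p = 0.46 with an estimated correlation), with 1 called over all genes, and 3 higher and 1 lower adjusted over the list alone. That camera call ended without transgenic rest array 11 (adjusted p = 0.0693), and the median turned to -0.039 in the 11 lymphocyte-high arrays (0.91) and was 0.13 in the 10 slow-high arrays (0.203).

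All 12 neutrophil markers were higher after the run in transgenic mice, with a median of 1.29 (camera adjusted p = 1.02e-07; adjusted p = 0.46 with an estimated correlation), with 0 called over all genes and 3 adjusted over the list alone. S100a9, an abundant neutrophil protein, differed by 2.61 (SE 0.95), S100a8 by 2.50 (SE 1.01), Retnlg by 1.81 (SE 0.58) and Lcn2 by 1.32 (SE 0.46), each at adjusted p = 0.84. The neutrophil median was 0.030 in the 13 lymphocyte-low arrays (camera adjusted p = 0.225) and 0.22 in the 10 slow-high arrays (0.0541). All 17 macrophage and monocyte markers were also higher (median 0.47, camera adjusted p = 3.53e-07; adjusted p = 0.46 with an estimated correlation), with 0 called by either count. Cd14 differed by 0.73 (SE 0.26) and Tyrobp by 0.84 (SE 0.42). Cytokines and chemokines had a median of 0.30 over 23 members (camera adjusted p = 1.07e-05; adjusted p = 0.46 with an estimated correlation), with 0 called by either count, and Il1b differed by 1.13 (SE 0.43). Beside these lists, 4 of 6 exercised against 2 of 6 unexercised transgenic arrays were high in lymphocyte markers. Between arrays high and low in lymphocyte markers, the neutrophil list differed by 1.22, the macrophage and monocyte list by 0.46 and the cytokine list by 0.31.

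Extracellular matrix and fibroblast genes were higher in 23 of 26 members (median 0.21, camera adjusted p = 1e-05; adjusted p = 0.46 with an estimated correlation), with 0 called by either count. Col4a2 differed by 0.38 (SE 0.18), Col1a2 by 0.40 (SE 0.20) and the collagen cross-linker Lox by 0.35 (SE 0.17). The integrated stress list had a median of 0.28 over 15 members (camera adjusted p = 0.00291; adjusted p = 0.46 with an estimated correlation), with 0 called over all genes and 1 lower adjusted over the list alone. Its members split, with Hspa5 at 0.60 (SE 0.25) and Pdia4 at 0.46 (SE 0.16) but the ATF4 target Chac1 at -1.36 (SE 0.40). Heat shock and chaperone genes had a median of 0.12, with 19 of 24 higher (camera adjusted p = 0.00342; adjusted p = 0.46 with an estimated correlation) and 0 called by either count. That call ended without transgenic exercised array 4 (adjusted p = 0.064) and with array weights (0.0587). Clock genes were lower in 11 of 12 members (median -0.35, camera adjusted p = 0.000251; adjusted p = 0.46 with an estimated correlation), with 0 called over all genes and 3 lower adjusted over the list alone. Ciart differed by -1.01 (SE 0.28), Dbp by -0.63 (SE 0.19) and Bhlhe40 by -0.48 (SE 0.17), while Arntl, which opposes them in phase, differed by 0.49 (SE 0.20). The clock list differed by 0.45 between arrays high and low in slow fibre genes. In subsets of arrays, the clock call ended in lymphocyte-low (0.0911) and slow-high arrays (0.0813), the cytokine call in lymphocyte-high arrays (0.0852), the matrix call in slow-low arrays (0.0614), and the integrated stress and chaperone calls in lymphocyte-high (0.0839 each) and slow-low arrays (0.315 and 0.0955).

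The interaction asked whether the transgene altered the response to the run, the question of the series. No single gene's response was found to differ between the genotypes: limma called 0 of 14984 genes, with 352 at an unadjusted p under 0.05 and a smallest adjusted p of 0.926. The genes with the smallest p were Hdac9, a histone deacetylase that represses muscle transcription, at -0.93 (SE 0.21), Wdr93 at -0.62 (SE 0.17) and Slc22a15 at -0.55 (SE 0.15), all at adjusted p = 0.926. Fuel metabolism genes were lower in the transgenic response in 19 of 22 members (median -0.27, camera adjusted p = 0.000535; adjusted p = 0.17 with an estimated correlation), with 0 called by either count. Pdk4 differed by -0.91 (SE 0.32), Pfkfb3 by -0.69 (SE 0.32), Ucp3 by -0.59 (SE 0.33) and Cpt1b by -0.52 (SE 0.26).

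All 12 neutrophil markers (median 1.22, camera adjusted p = 2.86e-05; adjusted p = 0.535 with an estimated correlation) and all 17 macrophage and monocyte markers (median 0.50, camera adjusted p = 4.45e-06; adjusted p = 0.535 with an estimated correlation) had higher values in the transgenic response, with 0 called by either count. S100a9 differed by 2.48 (SE 1.35), Retnlg by 1.79 (SE 0.82) and Tyrobp by 0.94 (SE 0.59). Matrix and fibroblast genes were higher in 23 of 26 members (median 0.26, camera adjusted p = 1.71e-05; adjusted p = 0.535 with an estimated correlation), with 0 called by either count; Col1a2 differed by 0.62 (SE 0.28) and Sparc by 0.39 (SE 0.20). Lymphocyte markers had the largest of these medians, 1.38 over 9 members (camera adjusted p = 0.0221; adjusted p = 0.607 with an estimated correlation), with 0 called by either count and Cd79b at 2.41 (SE 2.19). Lymphocyte-high arrays numbered 3 and 2 in wild type at rest and after the run, and 2 and 4 in transgenic mice. The lymphocyte camera call ended without any 1 of 8 arrays (adjusted p from 0.0569 to 0.107): wild-type rest arrays 6, 7 and 10, wild-type exercised array 5, transgenic rest arrays 8 and 11 and transgenic exercised arrays 3 and 8. It also ended with median scaling (0.187). The lymphocyte median was 0.012 in the 13 lymphocyte-low arrays (camera adjusted p = 0.952) and turned to -0.714 in the 11 lymphocyte-high arrays (0.0642). With both list means as covariates the neutrophil call ended (camera adjusted p = 0.0711), while the matrix call stayed (2.23e-09) and so did the fuel metabolism call (0.000229). With an estimated correlation 0 lists were called in that fit either. The fuel metabolism call ended in the 13 lymphocyte-low arrays (median -0.16, 0.402) and the 10 slow-high arrays (-0.18, 0.088), and the neutrophil median was 0.098 (0.289) in the lymphocyte-low arrays. The macrophage and monocyte median was 0.089 (0.86) in the 11 lymphocyte-high arrays and 0.16 (0.0533) in the 14 slow-low arrays.

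The exercise responses of the genotypes, which share no arrays, had a correlation across genes of -0.0902, and genes are not independent replicates. It came to 0.344 with both list means as covariates. Its sign turned on leaving out wild-type rest array 10 (0.32) or 7 (0.12), or wild-type exercised array 1 (0.17), 2 (0.15) or 3 (0.20). The calls had an overlap of 0 in each direction, which was fixed in advance because 0 genes were called in wild type.

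More single genes passed the test for genotype than for the run. Averaged over both exercise states, 36 genes differed between transgenic and wild-type muscle, 22 higher and 14 lower, with 486 at an unadjusted p under 0.05. The largest fitted rises among named genes were Cbwd1 by 2.25 (SE 0.46, adjusted p = 0.0268), Plek, a leukocyte and platelet protein, by 1.66 (SE 0.28, adjusted p = 0.00337), Clasrp by 1.51 (SE 0.29, adjusted p = 0.0196), Ush1c by 1.41 (SE 0.22, adjusted p = 0.0015) and Supt16, a histone chaperone, by 1.41 (SE 0.26, adjusted p = 0.0145). The largest falls were Hps5, a lysosome-related organelle factor, with -2.54 (SE 0.26, adjusted p = 4.73e-06), Ctu1, a tRNA-modifying enzyme, with -2.00 (SE 0.18, adjusted p = 5.75e-07), the potassium channel gene Kcna7 with -1.62 (SE 0.20, adjusted p = 8.19e-05), Ocel1 with -1.22 (SE 0.20, adjusted p = 0.00337) and Mgat4a with -0.71 (SE 0.14, adjusted p = 0.0212). In transgenic mice Hps5 was detected on 1 of 6 arrays at rest and 2 of 6 after the run, and Ctu1 on 1 and 3, so the sizes of these falls rest partly on background. In wild-type mice Plek was detected on 1 of 6 arrays at rest and 3 of 6 after the run, and Ush1c on 3 and 3. The probe ILMN_1217889, given next, was detected on 3 and 5 wild-type arrays. The sizes of these 3 rises therefore rest partly on background too. Among probes without a symbol, ILMN_1219510 was higher by 3.02 and ILMN_1217889 by 2.85, while ILMN_2603834 and ILMN_2603837 gave -2.09 and -2.21. All 36 calls stayed with both list means as covariates, when 106 genes were called. With the replicate number as a block, which leaves fewer residual degrees of freedom, only 5 genes were called. The calls of Cbwd1, Plek, Clasrp, Ush1c, Supt16, Kcna7, Ocel1 and Mgat4a then ended. The Cbwd1 call ended without any 1 of 8 arrays (adjusted p from 0.0501 to 0.0577): wild-type rest arrays 7 and 10, wild-type exercised arrays 1 and 3, and transgenic rest arrays 3, 4, 8 and 11. The Mgat4a call ended without wild-type rest array 7 (0.0522) or 10 (0.0526). The Cbwd1 call also ended with no filter on dim probes (0.0645), the Mgat4a call with median scaling (0.0889) and the Supt16 call with the mean of its probes (0.76, adjusted p = 0.0536).

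**Figure D3:**
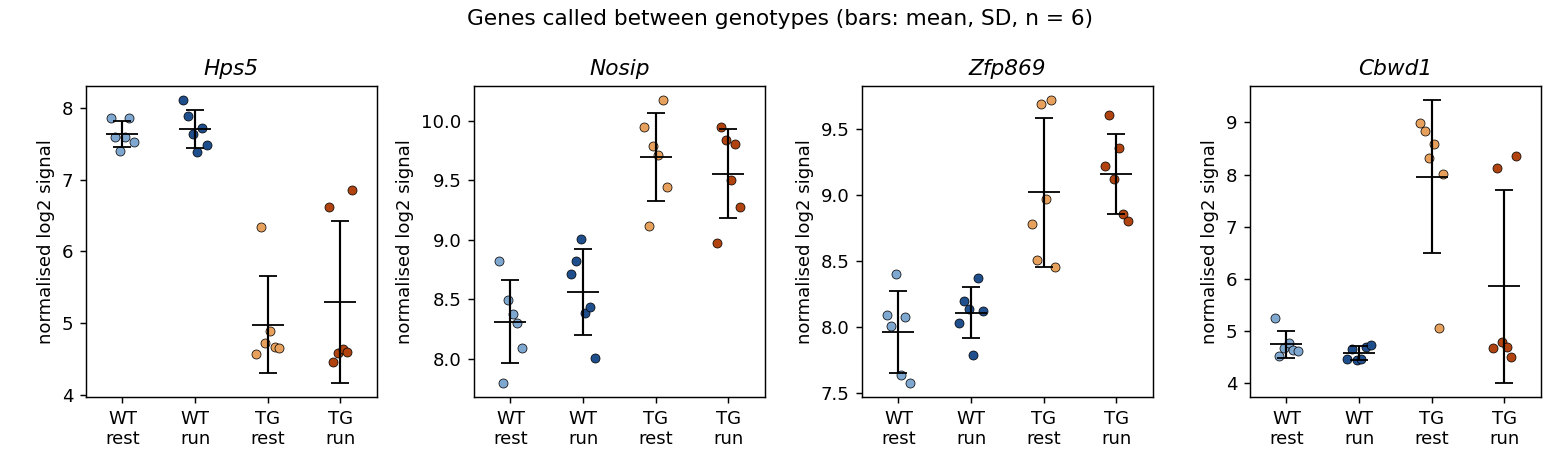
Normalised log2 signal of Hps5, Nosip, Zfp869 and Cbwd1 in each array by genotype and exercise; points are arrays, bars give the mean and SD of 6 arrays. Hps5 means are 7.64 and 7.71 in wild type against 4.98 and 5.29 in transgenic mice for the probe shown, while another Hps5 probe went the other way; Cbwd1 in transgenic mice splits into 7 high and 5 low arrays.

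Called genes crowded on a few chromosomes. Of the 29 called genes with a known chromosome, 11 lay on chromosome 8, where 1.53 would fall by chance, and 10 on chromosome 7, where 2.24 would. Another 3 lay on chromosome 14. In gene order, the chromosome 8 calls spanned 50 of 611 tested genes and those of chromosome 7 spanned 289 of 891. In 10000 random draws of 29 tested genes the fullest chromosome held at most 6 in 95% of draws (permutation p = 1e-04, the smallest they can give). Chosen after their values were seen, examples on chromosome 7 are Nosip, an inhibitor of nitric oxide synthase (1.19, SE 0.15), and Bcat2, a branched-chain amino acid transaminase (0.97, SE 0.12). On chromosome 8 they are the zinc finger genes Zfp869 (1.06, SE 0.15) and Zfp930 (0.98, SE 0.17) and the transcription factor gene Mef2b (-0.67, SE 0.11). Other probes of called genes moved the same way in 12 of 13 cases, 5 of them at an unadjusted p under 0.05. Both other Nosip probes did so (0.81 and 1.14), while those of Zfp869 (0.17 and 0.12), Mef2b (-0.068) and Supt16 (0.10) lay near 0 and that of Ang (0.22) was smaller than the called one (1.30). The exception was Hps5, whose second probe rose by 0.68 (SE 0.13, unadjusted p = 1.86e-05), and that probe took its place when detection on all 24 arrays was required. Cbwd1 was detected on 1 of 12 wild-type arrays, 0 of 6 after the run, and on 5 of 6 transgenic arrays at rest and 2 of 6 after the run, with means of 7.96 and 5.86. Its fitted size therefore rests on background, and against the detection floor it was at least 3.54-fold higher. Its signal in transgenic mice was either 8.01 to 8.98 or 4.50 to 5.05.

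Among the lists, tendon genes were lower in transgenic muscle in all 9 members (median -0.18, camera adjusted p = 0.000238; adjusted p = 0.673 with an estimated correlation). Comp, a cartilage and tendon matrix protein encoded on chromosome 8, fell by 0.69 (SE 0.14, adjusted p = 0.0212), was the 1 member called over all genes and was called adjusted over the list alone. Its call ended without wild-type exercised array 1 (adjusted p = 0.0514) or transgenic exercised array 1 (0.051). Chad differed by -0.42 (SE 0.21) and Col14a1 by -0.32 (SE 0.19). The tendon call ended in slow-high arrays (adjusted p = 0.206). The metallothionein call, given next, ended in lymphocyte-low arrays (0.152) and in slow-low arrays, where its median turned to -0.0631 (0.734). The metallothionein and glucocorticoid-responsive list had a median of 0.085 over 16 members (camera adjusted p = 0.00706; adjusted p = 0.673 with an estimated correlation), with 0 called over all genes and 1 adjusted over the list alone, Per1, at 0.71 (SE 0.17, adjusted p = 0.099). Per1 was called over all genes without wild-type rest array 11 (adjusted p = 0.0234) or transgenic exercised array 8 (0.0484). The list's camera call ended without transgenic rest array 4 (adjusted p = 0.062) or 5 (0.0862), with array weights (0.0565) and with 2 hidden factors (0.0571).

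At rest, transgenic muscle differed from wild type in 11 genes, 6 higher and 5 lower, with 448 at an unadjusted p under 0.05. Nosip rose by 1.39 (SE 0.21, adjusted p = 0.00197) and Bcat2 by 1.12 (SE 0.18, adjusted p = 0.00381). Zfp869 rose by 1.06 (SE 0.21, adjusted p = 0.0467) and Wdr93 by 0.60 (SE 0.12, adjusted p = 0.0461). The 2 other Nosip probes gave 0.73 and 1.27, and the 2 other Zfp869 probes only 0.24 and 0.20. Hps5 fell by 2.66 (SE 0.37, adjusted p = 0.000895, with its second probe opposite), Ctu1 by 2.11 (SE 0.26, adjusted p = 0.00013) and Kcna7 by 1.46 (SE 0.28, adjusted p = 0.0461). Macrophage and monocyte markers were lower in all 17 members (median -0.37, camera adjusted p = 4.12e-06; adjusted p = 0.54 with an estimated correlation), with 0 called by either count and Adgre1 at -0.50 (SE 0.27). Matrix and fibroblast genes were lower in 21 of 26 members (median -0.17, camera adjusted p = 8.08e-05; adjusted p = 0.54 with an estimated correlation), with 0 called by either count and Col1a2 at -0.68 (SE 0.20, adjusted p = 0.567). Tendon genes were lower in all 9 members (median -0.33, camera adjusted p = 0.000283; adjusted p = 0.54 with an estimated correlation), with 0 called over all genes and 1 adjusted over the list alone, Comp at -0.71 (SE 0.19). At rest 2 transgenic and 3 wild-type arrays were high in lymphocyte markers. Between arrays high and low in those markers the macrophage list differed by 0.46 and the tendon list by -0.40. The matrix call ended in slow-low arrays (0.0735) and the tendon call in slow-high arrays (0.195).

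With the replicate number as a block the count at rest came to 2 genes, and none of the 7 named genes was called. All 7 kept their direction at sizes near those without the block, which leaves fewer residual degrees of freedom. Nosip differed by 1.22 (adjusted p = 0.21), Ctu1 by -2.17 (0.21), Hps5 by -2.44 (0.253), Bcat2 by 1.03 (0.593), Wdr93 by 0.71 (0.593), Zfp869 by 0.95 (0.819) and Kcna7 by -1.46 (0.819). Calls near the threshold also depended on single arrays. The Zfp869 call ended on leaving out any 1 of 20 arrays (adjusted p from 0.0508 to 0.175), all but wild-type rest array 3, transgenic rest arrays 7 and 8 and transgenic exercised array 3. The Kcna7 call ended for 19 arrays (0.0541 to 0.146), all but transgenic rest array 8 and transgenic exercised arrays 1, 3, 8 and 11. The Wdr93 call ended for 19 arrays (0.0547 to 0.146), all but wild-type rest array 1, wild-type exercised array 9, transgenic rest array 8 and transgenic exercised arrays 3 and 5. The count of 11 came to 6 without wild-type rest array 10, and to 7 without wild-type rest array 6 or 7 or transgenic rest array 3. With only these 2 groups in the fit, the calls of Bcat2 (adjusted p = 0.0678), Kcna7 (0.162), Wdr93 (0.391) and Zfp869 (0.417) ended, with median scaling those of Zfp869 (0.188) and Wdr93 (0.246) ended, and with the mean of its probes Zfp869 differed by 0.50 (0.959). The Zfp869 call also ended with no background correction (0.0656), offset 50 (0.0536), no filter on dim probes (0.092) and detection on all 24 arrays (0.055). The Wdr93 call ended with no background correction (0.2), offset 50 (0.109) and the intensity trend with robust variance (0.0632). The Kcna7 call ended with no filter (0.092), detection on all 24 arrays (0.055) and array weights (0.0751).

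After the run, transgenic muscle differed from wild type in 13 genes, 8 higher and 5 lower, with 466 at an unadjusted p under 0.05. Supt16 rose by 2.02 (SE 0.37, adjusted p = 0.0262) and Ang, a secreted ribonuclease, by 1.85 (SE 0.27, adjusted p = 0.00156). Zfp869 rose by 1.05 (SE 0.21, adjusted p = 0.0409) and Use1 by 0.48 (SE 0.088, adjusted p = 0.0235). Second probes gave 0.021 for Supt16, 0.37 for Ang and 0.39 for Use1, and the 2 other Zfp869 probes gave 0.10 and 0.042. Hps5 fell by 2.41 (SE 0.37, adjusted p = 0.0033, with its second probe opposite), Ctu1 by 1.89 (SE 0.26, adjusted p = 0.000839), Kcna7 by 1.78 (SE 0.28, adjusted p = 0.00469) and Myh14, a non-muscle myosin, by 0.62 (SE 0.11, adjusted p = 0.0138). Myh14 was detected on 5 of 6 wild-type and 1 of 6 transgenic arrays, so this size rests on background; over both exercise states the bound was at least 1.10-fold lower. Heat shock and chaperone genes were lower in 20 of 24 members (median -0.10, camera adjusted p = 0.0273; adjusted p = 0.739 with an estimated correlation), with 0 called by either count and Hspa1a at -0.98 (SE 0.62). Neutrophil markers were higher in 10 of 12 members (median 0.66, camera adjusted p = 0.0273; adjusted p = 0.739 with an estimated correlation), with 0 called by either count and Lcn2 at 0.87 (SE 0.46). After the run 4 transgenic and 2 wild-type arrays were high in lymphocyte markers, and the neutrophil list differed by 1.22 between arrays high and low in them. With both list means as covariates these camera calls ended (adjusted p = 0.245 and 0.737). The neutrophil median turned to -0.0676 in lymphocyte-low arrays (camera adjusted p = 0.937) and to -0.173 in lymphocyte-high arrays (0.157). In lymphocyte-high arrays the chaperone median turned to 0.0901 (0.113).

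Several calls after the run also rested on single arrays. The Zfp869 call ended for 15 of 24 arrays left out (adjusted p from 0.0503 to 0.18): wild-type rest arrays 1, 6 and 10, all 6 wild-type exercised arrays, transgenic rest arrays 3 and 11 and transgenic exercised arrays 1, 3, 4 and 8. The Supt16 call ended without wild-type exercised array 1, 2 or 3 or transgenic exercised array 3, 8 or 11 (0.076 to 0.104). The Use1 call ended without wild-type exercised array 1, 2, 3, 6 or 9 or transgenic exercised array 3, 8 or 11 (0.0542 to 0.0955), and the Myh14 call without wild-type exercised array 2 or 3 or transgenic exercised array 3 (0.0555 to 0.0633). The count of 13 came to 7 without wild-type exercised array 1 or transgenic exercised array 8, and to 6 without wild-type exercised array 2 or 3 or transgenic exercised array 3. The chaperone call ended without wild-type exercised array 2, 3 or 5 or transgenic exercised array 1, 5 or 11 (0.0704 to 0.218). The neutrophil call ended without wild-type exercised array 1, 2, 3 or 5 or transgenic exercised array 1, 8 or 11 (0.0736 to 0.219). With median scaling the calls of Supt16, Zfp869 and Myh14 (adjusted p = 0.0533 each) and of Use1 (0.926) ended. With only these 2 groups in the fit, the calls of Hps5 (adjusted p = 0.13), Supt16 (0.13), Myh14 (0.138) and Use1 (0.279) ended, and with the mean of each gene's probes Zfp869 differed by 0.40 (0.997), Supt16 by 1.02 (0.183) and Use1 by 0.44 (0.644). With no filter on dim probes the Supt16 (0.0694) and Zfp869 (0.0889) calls ended, and the Myh14 call ended with no background correction (0.0809) and with offset 50 (0.0606).

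Of the genes called at rest and after the run, 3 were higher in both and 4 lower in both, against 0.0032 and 0.0017 for independent lists. The correlation of the at-rest and after-run differences across genes was -0.17, and 0.312 with both list means as covariates.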

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

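The tests of strain DNA, of the covariates against the genotype calls, of leukocytes drawn in by the run and of the order of the animals were chosen after the result was seen. A single array stood far from the 5 others of its group in 9 of 112 groups of 6 tested, where chance gives about 1 in 20. These were Itgb1 in transgenic exercised array 4 (log2 signal 8.394), Wdr93 in transgenic rest array 8 (5.143) and transgenic exercised array 5 (4.766), and Ocel1 in transgenic exercised array 4 (6.911). Cbwd1 stood apart in wild-type rest array 1 (5.242) and transgenic rest array 5 (5.049). Transgenic rest array 8 also stood apart for Hps5 (6.345), Ctu1 (6.018) and Kcna7 (7.798), each toward wild type. Transgenic exercised arrays 1 and 11 lay toward wild type too, for Hps5 (6.62 and 6.86) and Ctu1 (5.84 and 6.12). The median positions of the 3 genes were 0.485 in rest array 8, 0.544 in exercised array 1 and 0.437 in exercised array 11. Over the 7 other called genes of chromosome 7, the median position of rest array 8 between the wild-type mean (0) and the mean of the other transgenic arrays (1) was 0.724. The prediction asked that array 8 lie lower than every other transgenic array, and exercised array 11 lay lower, at 0.688. That array also lay toward wild type for Hps5 and Ctu1, and the test fails if another animal shares such a stretch. It could therefore not decide whether array 8 carries a partly wild-type stretch. Its median also pooled unlike genes, as seen afterwards. Nosip, Bcat2 and Ush1c lay at 0.553, 0.736 and 0.643 in rest array 8 and 0.432, 0.412 and 0.385 in exercised array 1. In exercised array 11 they lay at 0.688, 0.534 and 0.566. Sympk, Clasrp and Zfp93, first in gene order, lay at 0.516 to 1.03, 1.27 to 2.12 and 1.39 to 1.92 in these arrays. Myh14 lay at 1.09, 1.15 and 0.376.

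The response to the run differed between the genotypes by camera at the preset correlation for 14 lists, and for 0 with an estimated correlation, where the lowest adjusted p was 0.17. Their median interaction values were -0.265 for fuel metabolism, 0.163 for cytokines and chemokines, 1.22 for neutrophil, 0.499 for macrophage and monocyte, -0.514 for slow fibre, 0.259 for matrix and fibroblast and -0.405 for clock genes. The others were 0.295 for interferon-stimulated, -0.108 for respiratory chain, 0.256 for endothelial, 0.0868 for smooth muscle and pericyte, 0.824 for adipocyte, -0.351 for neuromuscular junction and 1.38 for lymphocyte genes.

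The genotype calls gathered on chromosomes 8 and 7. Lymphoid tissue or fibre mix in the samples is argued against, since all 36 calls stayed with both list means as covariates. A sequence variant under one probe stays open, since 5 of 13 second probes moved the same way at an unadjusted p under 0.05, which lies between its predictions. Strain DNA linked to the transgene or kept in the colony is a candidate explanation that was not tested apart from the pattern: the crowding that prompted it (permutation p = 1e-04, the smallest possible) does not set it apart from other causes of crowding. An effect of the transgene itself stays open and untested.

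Lymphocyte markers were high in 11 of 24 arrays. Leukocytes drawn in by the run are argued against as the whole source, since 5 of the 12 unexercised arrays were among the high ones. General infiltration cannot be told apart from other sources, since the macrophage and monocyte list differed by 0.455 against 3.45 for the lymphocyte list, between its predictions. Lymph node tissue taken with the muscle may account for the pattern: a node list written before its test differed by 2.41 between the arrays, with all 15 measured genes of 18 higher. Most of these are lymphocyte genes such as Cd22 and Blk, whose rise partly restates the split by lymphocyte markers. The list therefore does not set node tissue apart from other sources of lymphocytes. Its vessel genes Madcam1 and Chst4 differed by 1.09 and 1.07, and the chemokine gene Ccl21a by 1.88. Madcam1 and Chst4 read 4.59 and 4.465 in the low arrays, near background, so their sizes rest partly on it. Outside the list, Glycam1, Cxcl13 and Ccl19, chosen after their values were seen, differed by 7.96, 5.67 and 4.35. Fcmr, Cd79b and Cd3e, chosen likewise, differed by 6.00, 5.27 and 4.815. Whether these genes came from node tissue was not tested.

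Slow fibre genes were high in 10 arrays and low in 14. These 2 sets also differed in the lymphocyte list (-1.41) and the neutrophil list (-1.2). Over 4576 genes, the differences of 2 probes of 1 gene had a correlation of 0.545 (0.519 to 0.569 with 1 array left out). This is only a little above the bound of 0.5 that more soleus in the sample predicts. Between arrays high and low in lymphocyte markers the same correlation was 0.831. A lymphocyte difference thus moves 2 probes together as well. The value therefore cannot decide between more soleus and RNA quality or labelling acting on single probes. Both stay open. The mean label number was 3.2 in the high arrays and 7.29 in the low ones (permutation p = 0.00162), so the order in which animals were processed may also have a part, if the numbers follow it. A difference between animals in fibre type stays open and untested.

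The real counts were set beside those of 100 splits of the same arrays into groups of the same sizes, the real split included. For genotype at rest 11 genes were called, and 1 split, the real one, called as many (highest other 8). Genotype after exercise had 13 calls and 4 splits with as many (highest other 4738). Exercise over both genotypes had 2 calls and 2 such splits (highest other 6), and genotype over both exercise states 36 calls and 2 such splits (highest other 4335). With the replicate block the 3 genotype counts were 2, 2 and 5, and no splits were run. These shares are small but were not adjusted over the contrasts, and single splits called far more genes. Chance is therefore made less likely rather than excluded. For exercise in transgenic mice 1 gene was called and 6 splits called as many (highest other 734), so chance stays open. For exercise in wild type (0; highest other 3599) and the interaction (0; highest other 4445) the real count was 0, so all 100 splits called as many and the count of splits says nothing about chance. Limma gave 322 genes at an unadjusted p under 0.05 for exercise in wild type and 352 for the interaction. Both are below the share of 0.05 of all genes expected if none changed. Splits calling several times the real count point to a structure of the arrays other than their groups.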

How the results depend on the processing

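The covariates, the hidden factors and the subsets of arrays were chosen after the data were seen. The authors' processed values, the intensity trend with robust variance, no background correction, offset 50, no filter on dim probes, the mean of all detected probes and a limit of at least 1.5-fold moved no count of called genes by over 1.5 times. Over all alternatives, named genes kept direction and side of the threshold in 7488 values and lost a call in 266. They gained a call in 14, moved in 147 and reversed in 3. For lists the numbers were 1391, 128, 1, 30 and 13, in the same order. Most of the 187 gene results followed were not called in the main fit and so could not lose a call. The 7488 values therefore do not give the share of calls kept. Signal over background limits probes near detection. A slide block was not run, since slides are not given in the sources used here.

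Where a value moved, the cause was not tested, unless given. Median scaling: exercise in transgenic 0. Detection on all 24 arrays: genotype at rest 4, after exercise 8 genes; Hps5 0.89 at rest, 0.46 after exercise and 0.68 over both, since another probe was then used. All probes kept: genotype at rest 17. Array weights: exercise in wild type 2, over both 5, correlation of the exercise responses -0.465, Itga7 -0.045. Only the 2 groups compared: exercise in transgenic 0, genotype at rest 7, after exercise 6, with fewer arrays. Replicate block, with fewer residual degrees of freedom: exercise in transgenic 0, genotype at rest 2, after exercise 2, over both 5, correlation 0.553, Itga7 -0.074, slow fibre genes in wild type -0.106. The block ended the calls of Mt1 in transgenic mice (adjusted p = 0.0618), of all 8 genes named for genotype after exercise (0.11 to 0.983) and of Cbwd1 (0.439), Plek (0.577), Clasrp (0.764), Ush1c (0.0766), Supt16 (0.0885), Kcna7 (0.0885), Ocel1 (0.477), Mgat4a (0.607) and Comp (0.337) over both. It ended the described list calls of the adipocyte genes in wild type (median -0.055, adjusted p = 0.834) and of the slow fibre genes in wild type. The latter turned direction (camera adjusted p = 0.443). It gained 1 list call, the integrin-laminin and dystrophin-glycoprotein adhesion genes by genotype over both (median -0.0735, camera adjusted p = 0.0498, against 0.0069 and 1.0). At rest the shared numbers met the bound for pairing. In the other comparisons they did not (correlations of deviations -0.596 to 0.705). Of the arrays with a partner, 1 of 6 at rest, 2 of 6 for genotype after exercise, 2 of 6 for exercise in wild type and 2 of 10 in transgenic correlated best with their own number. At rest the block changed no described list call. False discovery rate 0.10: genotype over both 57; 0.01: exercise in transgenic 0, genotype at rest 6, after exercise 6, over both 19, by construction. Estimated correlation: 0 of 71 list calls.

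Lymphocyte covariate: exercise over both 9, genotype over both 58, correlation 0.166, lymphocyte interaction -0.0547. Both covariates: exercise in transgenic 3, genotype at rest 20, after exercise 29, exercise over both 31, genotype over both 106, correlation 0.344, lymphocyte interaction -0.0269; a list's value is near 0 by construction where its own mean is the covariate. With 2 hidden factors: 4, 23, 34, 31 and 116 in that order, correlation 0.293. The subsets hold fewer arrays. List calls ended with the camera direction kept in 10 cases in lymphocyte-low, 11 in lymphocyte-high, 13 in slow-low and 11 in slow-high arrays. A further 2, 5, 2 and 1 list calls, in the same order, ended with the direction turned. Among those with the camera direction kept, the clock median for exercise over both turned to 0.017 in lymphocyte-low arrays. The metallothionein median for exercise in transgenic turned to -0.039 in lymphocyte-high arrays. Lymphocyte-low (13 arrays): 0, 3, 2, 0 and 11, lymphocyte interaction 0.012, neutrophil genes by genotype after exercise -0.0676. Lymphocyte-high (11): 0, 4, 3, 0 and 4, correlation 0.242, slow fibre -0.156 and adipocyte genes 0.216 in wild type, lymphocyte interaction -0.714, and after exercise by genotype neutrophil -0.173 and heat shock genes 0.0901. Slow-low (14): 0, 2, 2, 0 and 4, list calls 36, correlation 0.616, adipocyte genes in wild type 0.0297, metallothionein list by genotype -0.0631. Slow-high (10): exercise in transgenic 0, genotype after exercise 8, exercise over both 0, genotype over both 22, neutrophil genes by exercise over both 0.0147.

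Leaving out 1 array gave 0 to 1 for exercise in wild type, 0 to 1 in transgenic, 0 for the interaction, 6 to 13 for genotype at rest, 6 to 16 after exercise, 2 to 4 for exercise over both, 28 to 40 for genotype over both, 61 to 82 list calls, correlation -0.39 to 0.315 and Itga7 0.014 to 0.208.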

Other observations

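The fits with covariates and the genes named from them were chosen after their values were seen. With the lymphocyte and slow fibre means as covariates, Ppargc1a, a coactivator of mitochondrial biogenesis, rose after the run over both genotypes by 0.99 (SE 0.16, adjusted p = 0.00657), against 1.12 (SE 0.21, adjusted p = 0.078) without them. Musk, the receptor kinase that organises the neuromuscular junction, rose by 0.83 (SE 0.13, adjusted p = 0.00372), and Crem, a cAMP-responsive transcription factor, by 0.78 (SE 0.15, adjusted p = 0.0256). Socs3 rose by 0.68 (SE 0.13, adjusted p = 0.0256), Ccl9 by 0.71 (SE 0.14, adjusted p = 0.0306) and Itga9, an integrin chain, by 0.37 (SE 0.076, adjusted p = 0.0415). Pfkfb3, which drives glycolysis, fell by 0.75 (SE 0.15, adjusted p = 0.0328) and the Wnt receptor gene Fzd9 by 0.66 (SE 0.13, adjusted p = 0.0276). Without covariates none of the last 7 was called (adjusted p from 0.252 to 0.99).

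Endothelial markers had higher values after the run in transgenic mice in 14 of 16 members (median 0.19, camera adjusted p = 0.000251; adjusted p = 0.46 with an estimated correlation). The endothelial list differed by -0.33 between arrays high and low in slow fibre genes, and 3 transgenic arrays at rest against 2 after the run were high in them. Respiratory chain genes had lower values in 24 of 26 members (median -0.084, camera adjusted p = 0.00109; adjusted p = 0.46 with an estimated correlation). That list differed by -0.13 between arrays high and low in lymphocyte markers, and 4 exercised against 2 resting transgenic arrays were high in them. With both covariates the 106 genotype calls included 29 genes of chromosome 7 and 22 of chromosome 8 among 86 with a known chromosome.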
